A study of Mus musculus with 9 samples.

How the data were processed

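Cells sorted as endothelial from the retinas of mouse pups at postnatal day 7 had their RNA sequenced in 3 groups of 3 libraries: controls, pups given antibodies against BMP9 and BMP10, and pups given these antibodies with a CDK4/6 inhibitor. Each library pooled 6 to 9 retinas. Per the submitters' processing notes, RNA was extracted with a spin column kit, libraries were run on an Illumina instrument, reads were converted with bcl2fastq 2.19.0, checked with FastQC and aligned with STAR 2.7 to GRCm39, and tested with DESeq2 in R 4.1. The counting tool, the annotation release and the strand setting are not given in the sources used here. The authors deposited 1 table of counts, unnormalised, with 55416 Ensembl gene identifiers and 9 columns, 1 per library. All values were whole numbers, and the columns were matched to the groups by their names. The replicate libraries differed in their counts by a chi-square of 13.52 to 110.98 per gene, far above counting noise.

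Symbols were taken from GENCODE M21, which is on the earlier build GRCm38, by Ensembl identifier, and 52083 identifiers (94%) had one. Because the builds differ, no coordinates are printed, and positions served only to find genes near each other. Total counts per library ran from 41.3 to 50.8 M, with means of 44.8 ± 3.24 M in controls, 43.8 ± 4.16 M in the antibody group and 49.5 ± 1.18 M in the inhibitor group. Counting error is therefore small for genes above a few CPM, and differences between replicate pools (a common biological coefficient of variation of 0.256) limit the precision.

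Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 22425. All 9 libraries were fitted together in edgeR 4.0.16 (TMM factors, glmQLFit, glmQLFTest, group as the only term, R 4.3.3), and the 3 comparisons were taken as contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. Log2 fold changes are given with standard errors (SE), and CPM as mean ± SD of 3 libraries. Each SE was derived from the test, as the absolute log2 fold change over the square root of its F statistic. Log2 CPM used a prior count of 2.

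For the genes of vessel biology, the cell cycle and signs of RNA quality, and for markers of the cell types a retinal sort could hold, 40 lists were written before the data were examined, as were the comparisons, the filter, the tests and most alternatives. Some genes stand in more than 1 list. Each list was tested with limma's camera (limma 3.58.1, 2-sided, preset correlation between genes of 0.01), adjusted over the 40 lists within each comparison, and again with a correlation estimated from the data. With the preset value 24 lists were called for the antibody group against controls, 17 for the inhibitor against the antibody group and 30 for the inhibitor group against controls, and with the estimated value 6, 4 and 0. Counts of called members are over all genes tested unless they are said to be adjusted over the list alone.

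The genes named were set by a rule: 24 anchor genes whatever their result, the 8 largest log2 fold changes in each direction among called genes with a mean of at least 5 CPM whose libraries did not overlap between the groups (chance gives 10% for 3 against 3), and up to 2 called genes per direction of each list by smallest p, or the smallest p where none was called. The text gives those of each group that matter, and says where another gene was added after its values were seen.

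The alternatives were DESeq2 size factors, upper-quartile factors, library totals alone, no filter, mean CPM of at least 1 or 5, robust estimation, a replicate block, the rod marker share as a covariate, each library left out in turn, only the 6 libraries compared, an added 2-fold minimum, an adjusted p under 0.01, the DESeq2 1.42.0 Wald test, limma-voom, and for the lists fry and lists without genes of other pathway lists. Scaling on endothelial markers, the mural marker share as a covariate and Y-linked expression as a covariate were chosen after seeing the data. The endothelial markers include members of other lists, among them Eng (SMAD1/5 targets), Kdr, Cd34 and Robo4 (tip cell), Sox17 (arterial and barrier) and Pecam1 and Cdh5 (flow). Scaling on them therefore holds part of those lists near 0 by construction. Where a marker share is named as a covariate, the value used was the mean log2 CPM of that list's markers. The mural value ran from 5.41 to 5.83 in controls, 6.83 to 7.565 in the antibody group and 4.31 to 4.66 in the inhibitor group. The rod value ran from 10.29 to 10.49 in controls, against at most 9.88 in any treated library. These covariates can remove much of any treatment effect, so that lost calls or changed signs under them do not show a role of cell composition.

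The pipeline was tested on simulated data in which 100 genes were changed 2-fold and 100 genes 1.5-fold, up or down, in 1 group. The 3 comparisons recovered 64%, 59% and 57% of the 2-fold changes and 19%, 14% and 17% of the 1.5-fold changes. They called 3, 8 and 4 unchanged genes, and 0 of 40 unchanged gene sets were called by camera. The simulated genes were drawn independently, whereas the estimated correlation within the real lists ran from -0.068 (lymphatic) to 0.891 (endothelial) for the antibodies against controls. The 0 of 40 therefore does not cover lists whose genes vary together. To judge how far the shared antibody libraries alone make the antibody and inhibitor effects opposite, 20 datasets were simulated in which the inhibitor changes nothing. These took the observed group means as true effects and drew each gene independently. On average they called 5456 genes for the antibodies against 4177 observed, so that they are only a rough reference for overlaps and correlations.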

Results

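RNA sequencing measured gene expression in cells sorted as endothelial from mouse retinas at postnatal day 7, in 3 groups of 3 libraries each. The pups were controls, pups given antibodies against BMP9 and BMP10 (the antibody group), or pups given the same antibodies and an inhibitor of CDK4 and CDK6 (the inhibitor group). BMP9 and BMP10 are ligands of the receptor ALK1 and its partner endoglin, whose genes are mutated in hereditary hemorrhagic telangiectasia, and CDK4 and CDK6 carry cells from G1 into S phase. Each library pooled 6 to 9 retinas, and no group received the inhibitor alone. The control libraries held 45.4, 47.7 and 41.3 M counts, the antibody libraries 41.3, 41.5 and 48.6 M, and the inhibitor libraries 49.2, 50.8 and 48.5 M. The first principal component of log2 CPM, the counts scaled to library size, held 27.3% of the variance and the second 22.6%.

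The libraries differed in the share of counts on cell type markers. Markers of pericytes and smooth muscle, the mural cells that wrap vessels, took 0.607% ± 0.066 of all counts in controls, 1.63% ± 0.317 in the antibody group and 0.18% ± 0.016 in the inhibitor group (mean ± SD, n = 3 libraries each). Endothelial markers took 0.418% ± 0.096, 0.546% ± 0.159 and 1.17% ± 0.063 in the same order. Rod photoreceptor markers took 3.63% ± 0.139, 2.11% ± 0.503 and 1.72% ± 0.179. Immediate early genes, which respond within minutes to stimulation or tissue handling, took 0.198% ± 0.008, 0.555% ± 0.096 and 0.237% ± 0.013. In every library the rod markers, at 1.59% to 3.78%, took more counts than the endothelial markers, at 0.327% to 1.23%. Such shares are of RNA and not of cells, and the sources used here do not give the purity of the sort. The pools also differed in sex: Xist, expressed from the inactive X chromosome, ranged over the libraries from 0.433 to 165 CPM and the Y-linked gene Ddx3y from 0.0394 to 133 CPM.

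**Figure D1:**
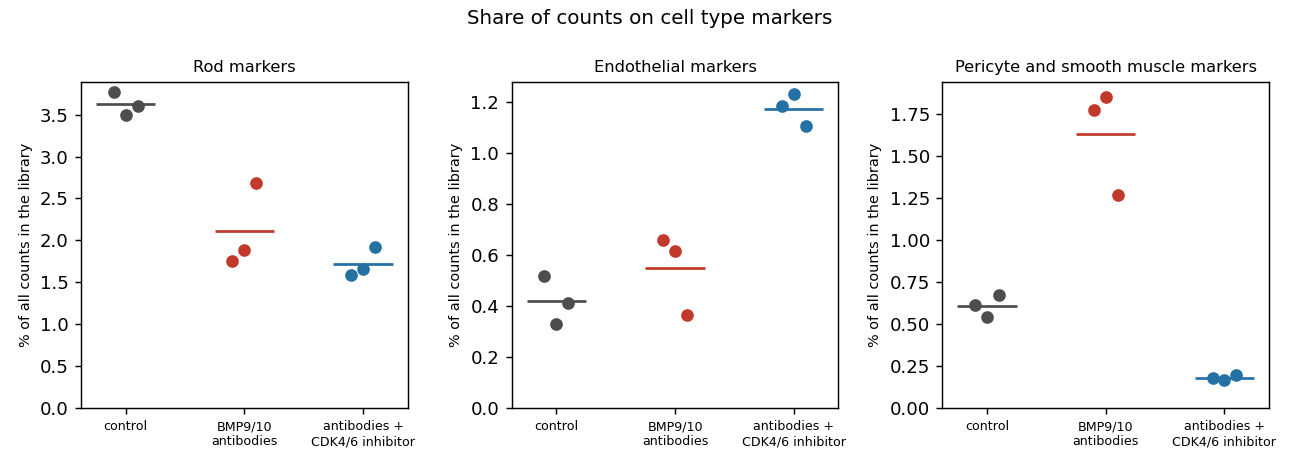
Share of all counts in each library (percent) on markers of rods, endothelial cells, and pericytes and smooth muscle. Points are libraries and lines are means of 3. Mural markers average 1.63% with the antibodies and 0.18% with the inhibitor added, and endothelial markers average 0.418% in controls and 1.17% in the inhibitor group.

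The comparison of the antibody group with controls asks what blocking BMP9 and BMP10 changes. Targets of SMAD1 and SMAD5, the transcription factors that BMP9 and BMP10 activate, were higher with the antibodies, not lower. Id1 (ENSMUSG00000042745), an inhibitor of differentiation and a SMAD1/5 target, stood at 97.6 ± 22.4 CPM in controls and 233 ± 50.6 CPM with the antibodies, a log2 fold change of 1.25 ± 0.18 (SE, n = 3 per group, adjusted p = 0.00135). Of the 20 SMAD1/5 target genes, 14 rose and the other 6 did not pass the test. The list's median log2 fold change was 1.15, and 0.74 when libraries were scaled on 16 endothelial markers, a scaling that moved the median of all genes from -0.02 to -0.40 and called 147 genes higher and 250 lower. The list's adjusted p was 5.99e-08 by its set test, and adjusted p = 0.154 with an estimated correlation. Id2 rose by 1.17 and Id3 by 1.12. The inhibitory SMADs Smad7 (ENSMUSG00000025880) and Smad6 rose by 1.36 ± 0.32 and 0.86 ± 0.22. Acvrl1, which encodes ALK1, rose by 0.96 ± 0.23 and Eng, which encodes endoglin, by 1.03 ± 0.22. Bmpr2, the type II receptor, had a log2 fold change of 0.63 (adjusted p = 0.0722), and Smad4, the shared partner of the SMADs, 0.26 (adjusted p = 0.254). The list of 18 BMP9/10 receptor pathway genes did not pass its test (adjusted p = 0.554). In it Eng, Acvrl1 and Bmp6 rose and Acvr2b fell by 0.85 on the log2 scale, with Bmp6, a BMP ligand, chosen after its values were seen (log2 fold change 3.28). Acvrl1 lost its call without control 2 (adjusted p 0.0667), control 3 (0.0585), antibody 1 (0.0618) or antibody 2 (0.056), Smad6 without control 1 (0.0599), control 2 (0.0843), antibody 1 (0.0793) or the inhibitor libraries (0.0695), Smad7 without control 1 (0.0532) or control 2 (0.0514), and Bmp6 without control 3 (0.0674), antibody 2 (0.0594) or the inhibitor libraries (0.0593). Smad7 stood at 0.83 without antibody 1, Bmpr2 was called without antibody 3 (7.54e-05) or by DESeq2 (0.0275), and 9 SMAD1/5 targets were called without control 1. After scaling on endothelial markers 1 of the 20 was. With the rod marker share as a covariate Acvrl1 (-0.18), Eng (-0.06) and Smad7 (-0.27) changed sign, as they did with the mural marker share (-0.72, -0.55 and -0.07), none of them then called. Over all genes 25 were called with the rod covariate and 3 with the mural one.

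Genes of the cell cycle rose together with the antibodies. Mki67 (ENSMUSG00000031004), a marker of proliferating cells, stood at 38.2 ± 10.3 CPM in controls and 120 ± 25.3 CPM with the antibodies, a log2 fold change of 1.65 ± 0.20 (adjusted p = 6.6e-04). Of 58 G2/M genes 51 rose, among them Ccnb2, a mitotic cyclin, by 1.54 and the spindle gene Tpx2 by 1.51. Anp32e alone fell, by 0.43 on the log2 scale. Of 47 G1/S genes 40 rose, among them Mcm2, a subunit of the replicative helicase, by 1.00 ± 0.10 and Gmnn, which blocks re-replication, by 1.36. In the cyclin D, CDK4/6 and RB list 13 of 25 rose, among them Ccnd1, encoding cyclin D1, by 0.64 and Cdk4 by 0.47 ± 0.08. The medians were 1.36 for G2/M, 0.97 for G1/S and 0.63 for the cyclin D list, and 0.91, 0.58 and 0.20 when scaled on endothelial markers. Their adjusted p were 1.69e-65, 1.52e-32 and 1.99e-09, and each had adjusted p = 0.0381 with an estimated correlation. So scaled, 4 G2/M, 1 G1/S and 1 cyclin D gene were called, all higher. Adjusted over the list alone, 14 SMAD1/5 targets, 53 G2/M, 42 G1/S and 17 cyclin D genes rose. Cdk6, the other kinase that the inhibitor targets, had a log2 fold change of 0.55 (adjusted p = 0.0565), and the CDK inhibitors Cdkn1a and Cdkn1b 0.63 (0.0535) and 0.31 (0.0651). Without antibody 3, Cdk6 (0.00207) and Cdkn1a (0.00493) passed, as did Cdkn1b without control 2 (0.0453), and by DESeq2 all 3 passed (0.0234, 0.017 and 0.0297), while Anp32e lost its call without control 2 (0.0787) or control 3 (0.0654). Of 43 replication-dependent histones, whose list did not pass (adjusted p = 0.313), 38 did not pass the test.

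Tip cell genes, those of the cells that lead a growing vessel sprout, were higher with the antibodies. Esm1 (ENSMUSG00000042379), a tip cell marker, stood at 3.73 ± 1.02 CPM in controls and 44.4 ± 5 CPM with the antibodies (log2 fold change 3.57 ± 0.22, adjusted p = 1.32e-05). Angpt2 (ENSMUSG00000031465), a destabilising ligand of the TIE2 receptor, rose by 1.96 ± 0.15, and Igfbp3 by 2.73 ± 0.14. Of 25 tip cell genes 19 rose and the other 6 did not pass, with a median of 1.09 (0.71 when scaled on endothelial markers, with 8 called higher and 0 lower). The list's adjusted p was 1.17e-23, and adjusted p = 0.0771 with an estimated correlation. Kdr, the main VEGF receptor of these cells, had a log2 fold change of 0.33 (adjusted p = 0.196). Plvap, which forms the diaphragms of fenestrated vessels, rose by 2.23 ± 0.18, and Tnfrsf9, a TNF receptor family member, by 4.16 ± 0.24.

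Genes of arteries and veins were both higher with the antibodies. They were not with the mural marker share as a covariate, whose values did not overlap between the groups. Both list tests then pointed down (arterial adjusted p 0.0495, venous 0.00106), and Gja4 (-0.16) and Nr2f2 (-0.57) changed sign without being called, in libraries where mural markers rose by 1.5. Over all genes 3 were called with that covariate. Nr2f2 changed sign with the rod marker share too (-0.04). The arterial connexins Gja4 (ENSMUSG00000050234) and Gja5 rose by 1.43 ± 0.24 and 2.82 ± 0.53, and Alpl fell by 1.05 on the log2 scale. Of 24 arterial genes 10 rose (median 0.63, adjusted p = 7.06e-04, adjusted p = 0.467 with an estimated correlation). Nr2f2, a transcription factor of venous identity, rose by 1.02 ± 0.21, as did 7 others of the 18 venous genes. The venous list had a median of 0.55 (adjusted p = 0.00278, adjusted p = 0.47 with an estimated correlation). Scaled on endothelial markers the medians were 0.22 and 0.09, with 1 arterial gene higher and 1 venous gene higher and 1 lower. Efnb2, the arterial ephrin, had a log2 fold change of 0.77 (adjusted p = 0.0502) and its venous receptor Ephb4 0.30 (0.54). Of 21 NOTCH pathway genes 8 rose and the other 13 did not pass (median 0.40, or -0.03 scaled on endothelial markers, adjusted p = 0.00282, adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone, 14 arterial, 9 venous, 20 tip cell and 9 NOTCH genes rose. Without the genes they share with other pathway lists, the arterial (adjusted p 0.962) and NOTCH lists (0.111) lost their call, as did the endothelial markers (0.509) and the VEGF and angiopoietin list (0.104). Without control 3 the arterial count was 6 and the NOTCH count 5, and without antibody 3 they were 16 and 13. Without antibody 1 the medians of the arterial, venous and NOTCH lists were 0.34, 0.30 and 0.25. Without antibody 3, Kdr (adjusted p 0.0326), Efnb2 (0.00755) and Ephb4 (0.00783) passed, and Efnb2 also by DESeq2 (0.0126).

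Mural, matrix and immediate early genes also rose. Of 17 pericyte and smooth muscle markers 15 rose and the other 2 did not pass, with a median of 1.5 (1.09 when scaled on endothelial markers, adjusted p = 1.78e-26, adjusted p = 0.0698 with an estimated correlation). Myl9 and Ndufa4l2 rose by 2.05 and 1.65, and Casq2, a calcium store protein of muscle, by 3.17. Of 23 mesenchymal and matrix genes 15 rose, among them Col1a1, a fibrillar collagen, by 2.66 (list median 1.06, or 0.63 scaled, adjusted p = 3.35e-13, adjusted p = 0.0892 with an estimated correlation). Of 20 immediate early genes 19 rose, among them Junb by 2.10, Zfp36 by 2.53, Fosb by 3.34 and Egr2 by 3.40 (list median 1.87, or 1.55 scaled, adjusted p = 2.42e-46, adjusted p = 0.0381 with an estimated correlation). The chemokines Cxcl1 and Ccl2 rose by 4.40 and 2.99, and the endothelial activation list that holds them had a median of 0.79 (0.36 scaled, adjusted p = 3.73e-08, adjusted p = 0.039 with an estimated correlation), with 12 of its 20 genes higher. Of 82 cytosolic ribosomal protein genes 71 rose (median 0.55, or 0.14 scaled, adjusted p = 7.48e-23, adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone, 16 mural, 18 mesenchymal, 19 immediate early, 14 activation and 76 ribosomal genes rose. Aqp1, a water channel, had the largest log2 fold change among the genes eligible to be named, 4.99 ± 1.27, with 154 ± 176 CPM in the antibody group, and lost its call without control 1 (adjusted p 0.0693), control 2 (0.0812), control 3 (0.0797) or antibody 1 (0.0756), with robust estimation (0.0506) and by limma-voom (0.162, log2 fold change 3.75), and its log2 fold change was -3.41 with the rod marker share as a covariate. After scaling on endothelial markers 9 mural, 2 mesenchymal, 9 immediate early, 2 activation and 0 ribosomal genes were called higher. Without control 2 or control 3 the ribosomal count was 44 or 47.

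Photoreceptor and pigment cell genes were lower with the antibodies. All 16 rod markers fell (median -0.77, or -1.07 scaled, adjusted p = 1.69e-14, adjusted p = 0.154 with an estimated correlation), among them Gnb1 by 0.73 and Gnat1, rod transducin, by 1.69 on the log2 scale. Opn1mw, a cone opsin, fell by 2.15 on the log2 scale. Pde6h, the cone phosphodiesterase subunit, fell by 4.20, from 97.2 ± 9.66 to 5.27 ± 0.947 CPM. Ttr fell by 3.73 and Pmel, a melanosome protein, by 3.10. Spp1 (log2 fold change -3.98), C1s1 (-3.06), Drd4 (-2.30) and Trpm1, a channel of bipolar cells (-1.33), fell too. Of the 16 endothelial markers 3 rose (median 0.35, or -0.06 scaled, adjusted p = 0.0131, adjusted p = 0.62 with an estimated correlation). Without control 2 (adjusted p 0.134), antibody 1 (0.103) or antibody 2 (0.0817) the endothelial list lost its call, as it did without genes shared with other pathway lists (0.509). With the rod (0.018) or mural marker share (1.07e-05) as a covariate its test pointed down, and without antibody 3 its median was 0.63, with 11 markers higher.

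Over all genes, 4177 of 22425 tested (18.6%) differed between the antibody group and controls at an adjusted p under 0.05, 2574 higher and 1603 lower. At least a 2-fold change was seen for 912 of the higher and 521 of the lower genes. The count was 2418 without control 2, 2333 without control 3 and 2698 without antibody 1. With the rod marker share as a covariate it was 25, with the mural marker share 3, and scaled on endothelial markers 397.

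**Figure D2:**
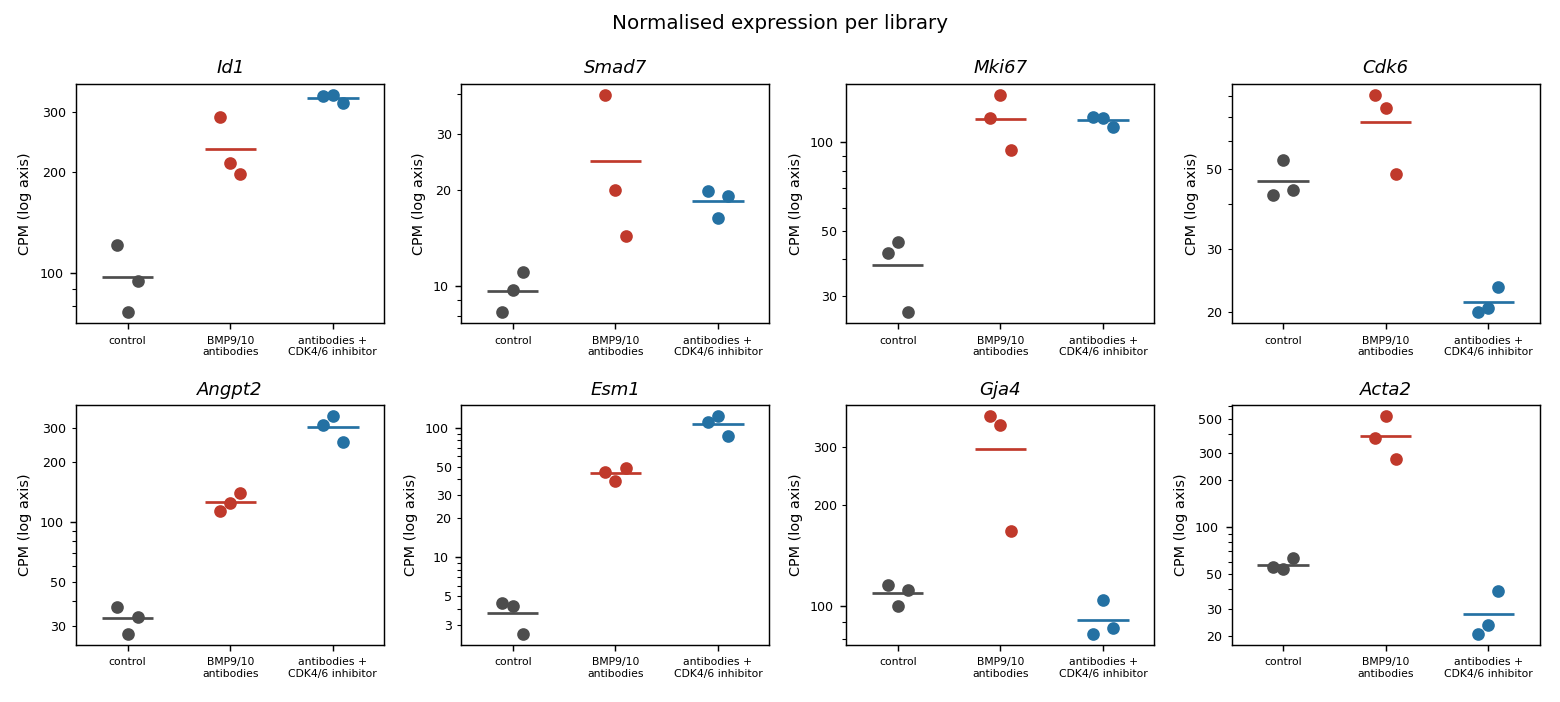
Expression of 8 genes in CPM (log axis) by group. Points are libraries and lines are means of 3. Id1, Mki67, Angpt2 and Esm1 are higher in both antibody-treated groups than in controls, Cdk6 is lowest with the inhibitor (21.4 CPM), and Gja4 and Acta2 have their highest means, 295 and 388 CPM, in the antibody group.

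The comparison of the inhibitor group with the antibody group asks what a CDK4/6 inhibitor changes when BMP9 and BMP10 are blocked. Proliferation genes were about as high with the inhibitor as without it. Mki67 stood at 118 ± 4.92 CPM with the inhibitor and 120 ± 25.3 CPM without it, a log2 fold change of -0.02 ± 0.20 (n = 3 per group, adjusted p = 0.967). The 58 G2/M genes had a median of -0.03 (adjusted p = 0.679), and -1.21 when scaled on endothelial markers, a scaling that moved the median of all genes to -1.22 and called 14608 of 22425 lower and 70 higher. Within the list Ncapd2 and Lbr rose by 0.48 and 0.52, and Cks2, Jpt1 and Psrc1 fell by 0.53, 0.44 and 0.56 on the log2 scale. The 47 G1/S genes had a median of 0.11 (-1.08 scaled), with 5 higher and the other 42 not passing, and the list passed its test upward (adjusted p = 0.0294, adjusted p = 0.677 with an estimated correlation). Among them were the helicase subunits Mcm2 (0.35) and Mcm3 (0.76), Dtl (0.91) and Exo1 (0.62). Psrc1, Dtl and Exo1 were chosen after their values were seen. Leaving out any 1 of the 9 libraries ended the call of at least 1 of these 4 genes (adjusted p 0.0534 to 0.204), and without inhibitor 1 or inhibitor 2 all 4 were lost. Exo1 stood at -0.88 with the mural marker share as a covariate, and scaled on endothelial markers 42 G1/S and 57 G2/M genes were called lower and 0 higher. The G1/S list lost its call without antibody 3 (adjusted p 0.0812) or inhibitor 1 (0.0924). Lbr lost its call without any library but antibody 2 (adjusted p 0.0533 to 0.173), Psrc1 without any but antibody 3 (0.0532 to 0.16), Cks2 without inhibitor 2 (0.0656) or inhibitor 3 (0.0744), and Jpt1 without inhibitor 2 (0.064). With Y-linked expression as a covariate the calls of Mcm2 (adjusted p 0.145), Mcm3 (0.0758), Dtl (0.0937), Exo1 (0.181), Lbr (0.167), Jpt1 (0.0549) and Psrc1 (0.0973) ended. Fitting only the 6 libraries compared ended those of Mcm2 (0.0786), Exo1 (0.0581), Lbr (0.0901) and Psrc1 (0.0645). Exo1 and Psrc1 also lost theirs with robust estimation (0.0537 and 0.0559) or with no expression filter (0.058 and 0.102), as did Mcm2 with no filter (0.0685), Exo1 with library totals alone (0.0585), and Psrc1 with DESeq2 factors (0.0588), upper-quartile factors (0.0545) or a mean of at least 5 CPM (0.0528).

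The CDK4/6 axis itself changed in both directions. Cdk6 (ENSMUSG00000040274), a target of the inhibitor, fell by 1.67 ± 0.18 on the log2 scale, from 67.8 ± 17 to 21.4 ± 1.88 CPM (adjusted p = 2.68e-04). Ccnd1 rose by 0.60 ± 0.13 and Cdkn1a, encoding the CDK inhibitor p21, by 0.83 ± 0.20. Cdk4 had a log2 fold change of 0.11 (adjusted p = 0.418) and Cdkn1b -0.33 (0.0693). E2f7, a repressor in the E2F family, rose by 0.85. Cdkn2a, the Ink4a and Arf locus, fell by 3.96, Ccnd2 by 1.03, E2f5 by 0.88 and Cdkn2d by 0.62 on the log2 scale, the last 3 chosen after their values were seen. The 25 genes of the cyclin D list had a median of 0.04 with a set test pointing down (adjusted p = 0.64), and a median of -1.13 scaled on endothelial markers, with 19 genes lower and 0 higher. So scaled, Ccnd1 (-0.59), Cdk4 (-1.08), Cdkn1a (-0.29) and E2f7 (-0.32) changed sign, and with the mural marker share as a covariate E2f7 (-0.18) and Ccnd2 (1.67) did, neither then called. With the mural covariate 0 genes were called in this comparison, so that Cdk6 and the other genes named here lost their calls too. With Y-linked expression as a covariate Ccnd1 (adjusted p 0.0684), Cdkn1a (0.0735) and E2f7 (0.0764) lost their calls. Without inhibitor 2, the calls of Ccnd1 (adjusted p 0.0737), Cdkn1a (0.0742), E2f7 (0.0912) and Cdkn2d (0.0526) ended. Ccnd1 also lost its call without inhibitor 1 (0.063), Cdkn1a without antibody 2 (0.0781), inhibitor 1 (0.0788) or inhibitor 3 (0.0651), and E2f7 without antibody 2 (0.0716) or inhibitor 3 (0.0509).

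The tip cell genes, already higher with the antibodies, were higher again with the inhibitor. Angpt2 rose by 1.25 ± 0.14, from 127 ± 13.1 to 302 ± 44.2 CPM (adjusted p = 3.51e-04), and Esm1 by 1.26 ± 0.19, though Esm1 stood at -0.67 and was not called with the mural marker share as a covariate. Under that covariate 0 genes were called in this comparison, so that Angpt2 lost its call as well. Apln, a tip cell ligand, rose by 1.74, Trp53i11 by 1.53 and Kdr by 1.23. Of 25 tip cell genes 14 rose and Pgf, placental growth factor, fell by 1.5 on the log2 scale. The list's median was 1.01. Scaled on endothelial markers it was -0.15, with 9 genes lower and 0 higher, against -1.22 and 14608 lower among all 22425 genes. The list's adjusted p was 3.49e-13 (adjusted p = 0.289 with an estimated correlation). In the same libraries 13 of 16 endothelial markers rose, with a median of 1.11 (adjusted p = 2.52e-15, adjusted p = 0.289 with an estimated correlation), among them Erg, an endothelial transcription factor, by 1.61. Plvap rose by 0.85. Genes of the blood-retina barrier and WNT signalling had a median of 0.79 (-0.31 scaled, adjusted p = 2.43e-08, adjusted p = 0.551 with an estimated correlation), with 12 of 29 higher, among them the WNT receptor Fzd4 by 1.02 and the lactate transporter Slc16a1 by 2.07. Flow-responsive genes had a median of 0.65 (-0.43 scaled, adjusted p = 4.83e-05, adjusted p = 0.551 with an estimated correlation), with 9 of 19 higher. Scaled on endothelial markers 2 barrier and 0 flow genes were higher, and 9 and 8 lower, and Fzd4 (-0.11) and Plvap (-0.28) changed sign. Adjusted over the list alone, 18 tip cell, 15 endothelial and 18 barrier genes rose. Without inhibitor 1 the endothelial, barrier and flow counts were 8, 3 and 5, and without inhibitor 2 they were 8, 3 and 4. The barrier count was also 5 without control 3 or antibody 2 and 6 without inhibitor 3, and without antibody 3 the barrier and flow medians were 0.50 and 0.39.

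Several arterial, venous and SMAD1/5 target genes fell with the inhibitor after having risen with the antibodies. With the mural marker share as a covariate, in libraries where mural markers had a median of -2.99, Gja4 (1.01), Gja5 (0.47), Nr2f2 (1.58) and Notch3 (0.31) changed sign and were not called. Neither was any other gene of this comparison, with 0 called over all genes. Gja4 fell by 1.69 ± 0.25, from 295 ± 111 to 91.2 ± 11.7 CPM (adjusted p = 0.00165), against 109 ± 8.13 CPM in controls. Gja5 fell by 2.5 ± 0.52 and Nr2f2 by 1.09 ± 0.21 on the log2 scale. Hey2, an arterial NOTCH target, fell by 2.31. Of the 20 SMAD1/5 target genes Gja4, Gja5, Hey2 and Bmper (-1.87) fell, while Eng (1.12 ± 0.22), Lfng (0.87) and Bambi (0.85) rose, Bmper and Bambi chosen after their values were seen. That list had a median of -0.37 (-1.51 scaled, with 15 lower and 0 higher, adjusted p = 0.119). Id1 (0.51, adjusted p = 0.0942), Id3 (-0.26, 0.415), Smad6 (0.03, 0.961) and Smad7 (-0.42, 0.452) did not pass, nor did Acvrl1 (0.75, 0.0596), Bmpr2 (0.49, 0.192), Smad4 (-0.30, 0.248) or the receptor pathway list (adjusted p = 0.0687). Ephb4 rose by 1.09 ± 0.31 (adjusted p = 0.0486) and Efnb2 had a log2 fold change of -0.05 (0.928). The arterial list, with 5 genes higher and 6 lower, had a median of 0.07 with a set test pointing down (adjusted p = 0.64), and a median of -1.06 scaled, with 13 lower and 0 higher. The venous list had a median of 0.81, with 8 of 18 higher and 3 lower, and a median of -0.32 scaled, with 1 higher and 6 lower (adjusted p = 0.0306, adjusted p = 0.677 with an estimated correlation). In the NOTCH list Notch3 and Heyl, both of mural cells, fell by 3.37 and 2.91 on the log2 scale (list adjusted p = 0.121, median -0.18, or -1.38 scaled). Without antibody 3 the SMAD1/5 list passed its test downward (adjusted p 0.00277), with 7 genes lower, as did the arterial (0.0102) and NOTCH lists (8.69e-05), the last also without genes shared with other pathway lists (0.00384), and the venous list lost its call (0.312), as it did without genes shared with other pathway lists (0.328) or with Y-linked expression as a covariate (0.0588). Without inhibitor 1 the SMAD1/5 list passed too (0.0375), and without antibody 1 its median was -0.17, the arterial median 0.38 and the Gja5 value -1.62. Gja5 lost its call without inhibitor 2 (0.0583) and Bambi without any library but control 1 and antibody 1 (0.0503 to 0.136). Ephb4 lost its call without any library but antibody 2 and antibody 3 (0.0588 to 0.124), and the venous count was 3 without inhibitor 1 or inhibitor 2. Bambi and Ephb4 also lost their calls with Y-linked expression as a covariate (0.129 and 0.11) or with only the 6 libraries compared (0.0573 and 0.0808). The receptor pathway list passed without antibody 2 (0.0158) or inhibitor 3 (0.0407). Without antibody 1, Acvrl1 (0.0428) and Id1 (0.0252) passed, and without antibody 3 Acvrl1 (0.0484) and Id3 (0.0428) passed. By DESeq2 Acvrl1 (0.00966) and Id1 (0.0356) passed, as they did by limma-voom (0.0304 and 0.0478).

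Mural cell genes were far lower with the inhibitor. Rgs5, a pericyte marker, fell by 3.46 ± 0.16 on the log2 scale, and Acta2 (ENSMUSG00000035783), smooth muscle actin, fell by 3.81 ± 0.28. Des (-3.63) and Higd1b (-3.77) fell as far. Of 17 mural markers 15 fell and the other 2 did not pass (median -2.99, or -4.11 scaled, adjusted p = 1.46e-83, adjusted p = 0.0291 with an estimated correlation). Fam162b (log2 fold change -4.92), Rrad (-4.27), Pik3cd, a phosphoinositide kinase subunit (-4.01), Casq2 (-4.01), Rem1 (-3.93) and Pla1a (-3.81) fell by similar amounts. Of 23 mesenchymal and matrix genes 10 fell, and the list passed its test downward (adjusted p = 1.8e-04, adjusted p = 0.436 with an estimated correlation) with a mean of -0.78 and a median of 0.03 (-1.15 scaled). Of 20 immediate early genes 18 fell (median -1.14, or -2.43 scaled, adjusted p = 1.56e-29, adjusted p = 0.0351 with an estimated correlation), among them Junb by 1.66 and Zfp36 by 1.69 on the log2 scale. Cxcl1 fell by 3.40 and Ccl2 by 2.21. Adjusted over the list alone, 16 mural and 20 immediate early genes fell. Genes that had been low with the antibodies rose, among them Ttr by 3.99, Pmel by 3.53, Pde6h by 3.00 and Rgr, an opsin of the pigment epithelium, by 2.97. Fndc1 rose by 2.23 and Ly6a by 1.95.

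Over all genes, 2543 of 22425 (11.3%) differed between the inhibitor and antibody groups, 1156 higher and 1387 lower. The count was 1436 without inhibitor 1, 1297 without inhibitor 2 and 1675 without inhibitor 3. It was 1418 with Y-linked expression as a covariate, 14678 (70 higher) scaled on endothelial markers, and 0 with the mural marker share as a covariate (edgeR, with 2596 at an unadjusted p under 0.05), against 3811 by DESeq2 and 2836 by limma-voom without that covariate. Of the 4177 genes that differed between the antibody group and controls, 854 were called in the opposite direction with the inhibitor, 647 up then down and 207 down then up. A further 199 were called in the same direction again, 171 up and 28 down. Independent lists would share 159, 83, 133 and 99 in the same order, a reference that leaves out the shared antibody libraries. Data simulated with an inhibitor that changes nothing, which keep the shared libraries, gave 0.15 opposite and 0 further calls, few by construction. Leaving out 1 library gave 535 to 1289 opposite and 61 to 310 further calls. Of the 4177 genes 65.6% had opposite signs in the 2 comparisons, against 62.2% where data were simulated with an inhibitor that changes nothing.

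The comparison of the inhibitor group with controls asks which differences were present when both treatments were given. Tip cell genes stood far above controls. Esm1 rose by 4.83 ± 0.23, from 3.73 ± 1.02 to 106 ± 18.5 CPM (n = 3 per group, adjusted p = 4.4e-06), Angpt2 by 3.21 ± 0.15 and Igfbp3 by 3.80 ± 0.14. Of 25 tip cell genes 24 rose (median 1.61, adjusted p = 1.53e-48, adjusted p = 0.0572 with an estimated correlation), among them Kdr by 1.56 and Cd34 by 2.04. Scaled on endothelial markers, which moved the median of all genes to -1.65 and called 17464 of 22425 lower, the tip cell median was 0.06, with 9 genes higher and 4 lower. All 16 endothelial markers rose, with a median of 1.52 (adjusted p = 5.01e-19, adjusted p = 0.18 with an estimated correlation). Plvap rose by 3.08 ± 0.18 and Tnfrsf9 by 5.37 ± 0.25. Acer2, a ceramidase, rose by 3.37, Upp1, uridine phosphorylase, by 3.07 and the kinase Sgk1 by 2.87. Of 19 flow-responsive genes 17 rose (median 1.02, or -0.55 scaled, adjusted p = 3.66e-12, adjusted p = 0.212 with an estimated correlation), among them Cav1, the caveolar coat protein, by 2.28. Of 29 barrier and WNT genes 18 rose (median 1.02, or -0.51 scaled, adjusted p = 1.3e-08, adjusted p = 0.354 with an estimated correlation), among them Fzd4 by 1.5. So scaled, 2 flow genes were higher and 9 lower, and 0 barrier genes higher and 14 lower. With the rod marker share as a covariate the barrier list test pointed down (adjusted p 0.0217). The barrier count was 10 without control 2, control 3 or inhibitor 2 and 11 without inhibitor 1.

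Cell cycle genes were also above controls in the inhibitor group. Mki67 rose by 1.63 ± 0.20 (adjusted p = 4.2e-04), Mcm2 by 1.35 ± 0.10, Ccnb2 by 1.71, Gmnn by 1.47 and Ccne1, cyclin E1, by 1.94. Of 47 G1/S genes 43 rose (median 1.06, or -0.56 scaled, adjusted p = 8.21e-37, adjusted p = 0.0572 with an estimated correlation). Of 58 G2/M genes 50 rose (median 1.24, or -0.37 scaled, adjusted p = 5.05e-50, adjusted p = 0.0781 with an estimated correlation). Of the 25 cyclin D genes 14 rose, among them Ccnd1 by 1.24, Cdk4 by 0.58 and Cdkn1a by 1.46, and 5 fell, among them Cdk6 by 1.12 ± 0.18 on the log2 scale (median 0.58, or -1.01 scaled, adjusted p = 2.12e-06, adjusted p = 0.0884 with an estimated correlation). Cdkn1b had a log2 fold change of -0.02 (adjusted p = 0.895). With endothelial scaling 20 G1/S, 17 G2/M and 15 cyclin D genes were called lower and 0 higher, where 17464 of all 22425 genes were lower. Adjusted over the list alone, 44 G1/S, 52 G2/M and 24 tip cell genes rose.

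SMAD1/5 targets and vessel identity genes differed from controls in part. Id1 rose by 1.76 ± 0.18 (adjusted p = 1.8e-04), Id3 by 0.87 and Smad6 by 0.89, while Smad7 had a log2 fold change of 0.94 (adjusted p = 0.052). Acvrl1 rose by 1.71, Eng by 2.15 and Bmpr2 by 1.13, and Smad4 had a log2 fold change of -0.04 (0.89). Of the 20 SMAD1/5 targets 9 rose, 10 adjusted over the list alone, and Hey2 (-1.39), Id4 (-0.98) and Cdkn1c (-0.57) fell, Cdkn1c chosen after its values were seen. The list's median was 0.80 (-0.77 scaled, with 2 higher and 13 lower, adjusted p = 0.00144, adjusted p = 0.312 with an estimated correlation). Gja4 (-0.26, adjusted p = 0.477), Gja5 (0.32, 0.698), Nr2f2 (-0.07, 0.847) and Efnb2 (0.72, 0.0535) did not pass, and Ephb4 rose by 1.39. Of 24 arterial genes 12 rose and 4 fell (median 0.74, or -0.86 scaled, with 1 higher and 15 lower, adjusted p = 0.0129, adjusted p = 0.497 with an estimated correlation), and of 18 venous genes 10 rose and 2 fell (median 1.07, or -0.51 scaled, with 3 higher and 9 lower, adjusted p = 3.33e-06, adjusted p = 0.292 with an estimated correlation). With the rod marker share as a covariate the arterial test pointed down (adjusted p 0.00291), and Bmpr2 (-0.51), Id3 (-0.28), Ephb4 (-0.51) and Cdkn1c (0.15) changed sign without being called. Over all genes 6 were called with that covariate. Smad6 lost its call without control 2 (adjusted p 0.0629), and Smad7 was called without antibody 1 (0.00397) or antibody 3 (0.0132), as was Efnb2 (0.00288 and 0.0189), and both were called by DESeq2 (0.00977 and 0.0134). Id4 lost its call without control 2 (0.0558), control 3 (0.0983), inhibitor 2 (0.0898) or inhibitor 3 (0.0852), and Cdkn1c without control 1 (0.0932), control 2 (0.0615), control 3 (0.11), inhibitor 2 (0.137) or inhibitor 3 (0.0855). With Y-linked expression as a covariate Id4 (0.099) and Cdkn1c (0.135) lost their calls, as did Cdkn1c with no expression filter (0.0567). The arterial count was 7 without control 3, inhibitor 1 or inhibitor 2, and the arterial list lost its call without genes shared with other pathway lists (0.365), as did the receptor pathway (0.365), VEGF and angiopoietin (0.183) and fibroblast lists (0.488).

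Mural, rod and neuronal genes were below controls. Of 17 mural markers 14 fell and 1 rose (median -1.56, or -3.07 scaled, adjusted p = 1.29e-15, adjusted p = 0.18 with an estimated correlation). Rgs5 (-1.98) and Des (-1.97) were among those that fell. All 16 rod markers fell (median -1.02, or -2.59 scaled, adjusted p = 2.32e-17, adjusted p = 0.18 with an estimated correlation), among them Gnb1 by 0.84 on the log2 scale. Among other genes that fell were Fam162b (-3.13), Spp1 (-2.93, or 1.30 with the rod marker share as a covariate), Nefl, a neurofilament of ganglion cells (-2.67), Ccdc80 (-2.63), the laminin Lamc3 (-2.59), the integrin Itga8 (-2.56), Atp13a5 (-2.48) and Pik3cd (-2.47). The mitochondrially encoded genes had a median of -0.45 (-2.02 scaled, with 13 of 13 lower, adjusted p = 0.0016, adjusted p = 0.426 with an estimated correlation).

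Over all genes, 5562 of 22425 (24.8%) differed between the inhibitor group and controls, 2985 higher and 2577 lower, with 1299 and 865 changed at least 2-fold. Of the genes higher with the antibodies than in controls, 1479 were also higher in this comparison, and of the lower ones 847 were also lower, against 343 and 184 for independent lists, though the shared control libraries alone add to the overlap. Data simulated with an inhibitor that changes nothing gave 2388 and 1763, but they also called more genes for the antibodies, 5456 on average against 4177. Of the 854 genes called in opposite directions above, 382 that had risen and 182 that had fallen were not called against controls in the inhibitor group. A gene not called can still differ, and 476 of them had a log2 fold change within 0.5 of 0 there. The count of 5562 was 3602 without control 3, 3546 without inhibitor 1 and 3510 without inhibitor 2. It was 6 with the rod marker share as a covariate, 1757 with the mural marker share, 3489 with Y-linked expression, and 17565 scaled on endothelial markers.

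**Figure D3:**
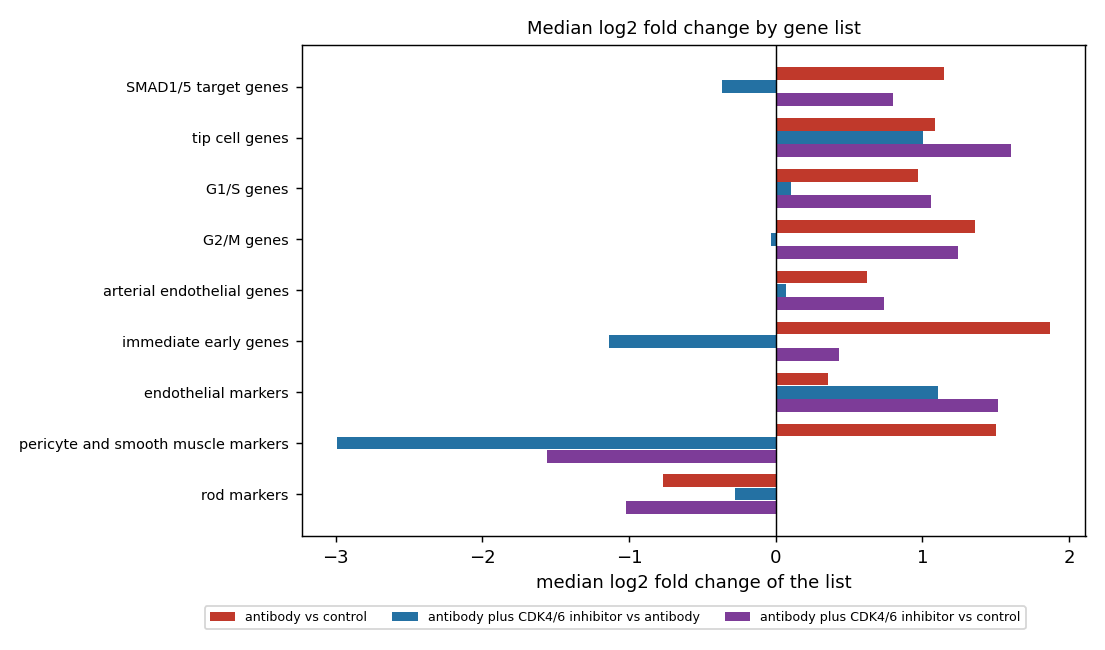
Median log2 fold change of 9 gene lists in the 3 comparisons. Tip cell genes are above 0 in all 3 comparisons (1.09, 1.01 and 1.61), whereas G2/M genes are near 0 between the inhibitor and antibody groups (-0.03) and mural markers there lie at -2.99. Scaled on endothelial markers the tip cell median between the inhibitor and antibody groups is -0.15.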

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

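Scaling on endothelial markers, the mural marker covariate and the Y-linked covariate were chosen after seeing the data. The counts of genes called kept within 1.5 times their value with DESeq2 or upper-quartile factors, library totals, no filter, either CPM minimum, robust estimation, the 6 libraries compared, DESeq2's test and limma-voom. The replicate numbers are not stated to mark a shared day or litter. Correlations of residuals between groups ran from -0.03 to 0.071 for same-number libraries and from -0.08 to 0.077 for others, so that no pairing was seen. With a replicate block the counts were 4237, 2526 and 5531, within 1.5 times as well. With the block Aqp1 lost its call for the antibodies against controls (adjusted p 0.0525) and Cdkn1a gained one (0.0499). For the inhibitor against the antibodies Acvrl1 (0.038) and Id1 (0.0354) gained theirs. Of the list tests 3 gained a call and 1 lost one. With library totals alone the share of higher genes fell from 61.6% to 49.1% for the antibodies against controls and from 53.7% to 41.7% for the inhibitor group against controls, and the median of all genes moved to -0.10 and -0.16. The self-test recovered at most 64% of 2-fold and 19% of 1.5-fold changes, so that smaller changes are often missed at this number of libraries. Where a setting below moved a value, the cause was not tested, except that stricter thresholds call fewer genes by construction, and that scaling on markers that differ between groups shifts all genes.

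In the order antibody against control, inhibitor against antibody, and inhibitor against control, the genes called were 25, 2280 and 6 with the rod covariate, 397, 14678 and 17565 with endothelial scaling, and 3, 0 and 1757 with the mural covariate (edgeR, with 2596 at an unadjusted p under 0.05 for the 0). They were 3573, 1418 and 3489 with the Y-linked covariate, 1433, 1172 and 2164 with the 2-fold minimum, and 1660, 1109 and 2887 at an adjusted p under 0.01. Leaving out 1 library gave 2333 to 6135, 1297 to 2772 and 3510 to 6768. The lists called were 6, 4 and 0 with the estimated correlation (camera, against 24, 17 and 30), 17 for the inhibitor group against controls with the rod covariate, and 31 for the inhibitor against the antibody group by fry's mixed test. Of the genes that responded to the antibodies, 514 were called opposite with the inhibitor at an adjusted p under 0.01, 457 with the 2-fold minimum and 535 to 1289 without 1 library, and 93, 50 and 61 to 310 were called further. The share with opposite signs was 76.69% with the 2-fold minimum and 62.13% to 71.76% without 1 library, and the median ratio of the inhibitor group's to the antibody group's change from control was 0.614 and 0.648 to 0.816. That ratio, of changes that share the controls, was 0.767 with the settings used throughout and 0.929 where an inhibitor that changes nothing was simulated.

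Across genes, which are not independent replicates, the covariance of the antibody and inhibitor effects was -0.359. It was -0.146 with no effects simulated and -0.157 with an inhibitor that changes nothing. Without 1 library it was -0.762 to -0.42. All fits without 1 library let more genes through the filter, 23315 to 23436 against 22425, so that their ranges mix a changed gene set with the omission. The correlation was -0.47, against -0.518 to -0.479 with no effects simulated and -0.299 to -0.239 with an inhibitor that changes nothing. The covariance of the 2 differences from controls was 0.403, and 0.464 to 0.646 without 1 library, against 0.144 with no effects simulated and 0.923 with an inhibitor that changes nothing. The correlation there was 0.514, against 0.469 to 0.527 and 0.852 to 0.865 in the same simulations. Both correlations lie outside the ranges for an inhibitor that changes nothing, and the second lies inside the range with no effects. The simulated antibody effects took the observed means as true and gave 5456 called genes against 4177 observed. They are therefore not a like reference, and no conclusion is drawn. Over the genes with a mean of at least 5 CPM, for which nothing was simulated, the covariances were -0.104 and 0.194.

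Calls that reversed were all under a composition covariate or endothelial scaling. The mural values did not overlap between the groups, nor did the rod values of controls with those of the treated groups. Reversals under these covariates therefore do not show a cause. List tests reversed for the antibodies against controls with the rod covariate (endothelial markers 0.018, microglia 0.038) and the mural covariate (arterial 0.0495, venous 0.00106, flow 0.0484, endothelial 1.07e-05), and for the inhibitor group against controls with the rod covariate (arterial 0.00291, barrier 0.0217, bipolar 0.00225, microglia 0.0198) and endothelial scaling (ribosomal 0.0187). Named genes changed sign in the comparison of the antibodies with controls with the rod covariate for Acvrl1 (-0.18), Eng (-0.06), Smad7 (-0.27), Nr2f2 (-0.04), Aqp1 (-3.41), and with the mural covariate for Acvrl1 (-0.72), Eng (-0.55), Smad7 (-0.07), Gja4 (-0.16), Nr2f2 (-0.57). Signs changed in the comparison of the inhibitor with the antibodies with the mural covariate for Gja4 (1.01), Gja5 (0.47), Nr2f2 (1.58), Esm1 (-0.67), E2f7 (-0.18), Pgf (0.64), Notch3 (0.31), Ccnd2 (1.67), Exo1 (-0.88), Il17rc (0.05), Efcab12 (-0.51), and with endothelial scaling for Bmpr2 (-0.59), Id1 (-0.65), Smad6 (-1.12), Ccnd1 (-0.59), Cdk4 (-1.08), Cdkn1a (-0.29), Mcm2 (-0.83), Plvap (-0.28), Lfng (-0.27), E2f7 (-0.32), Mcm3 (-0.39), Ncapd2 (-0.73), Lbr (-0.63), Fzd4 (-0.11), Bambi (-0.26), Dtl (-0.24), Exo1 (-0.62), Efcab12 (-0.13). Signs also changed in the comparison of the inhibitor group with controls with the rod covariate for Bmpr2 (-0.51), Id3 (-0.28), Ephb4 (-0.51), Spp1 (1.30), Cdkn1c (0.15), and with endothelial scaling for Bmpr2 (-0.46), Id3 (-0.71), Smad6 (-0.68), Ccnd1 (-0.39), Cdk4 (-1.01), Cdkn1a (-0.09), Mcm2 (-0.25), Gja5 (-1.20), Efnb2 (-0.88), Ephb4 (-0.15), Gmnn (-0.13), Fzd4 (-0.06). Over these 3 settings the other values of named genes kept their side of the threshold 260 times, lost their call 229 times and gained one 10 times. Over all remaining settings the named genes did so 3693, 129 and 53 times and the list tests 1747, 103 and 70 times. Genes under a CPM minimum have no value there. With both libraries of a group left after 1 is omitted, the fit pools their spread with the other groups.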

Other observations

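The tests of mural RNA, endothelial share and cone cells below were chosen after the results were seen, and the test around Gt(ROSA)26Sor was written before its result. Markers of pigment epithelium and melanocytes, which lie behind the retina, were lower in the antibody group than in both other groups. Against controls their median was -2.58 with the antibodies (adjusted p = 5.23e-08, adjusted p = 0.0416 with an estimated correlation), with 6 of 9 lower, and with the inhibitor added it was 2.97 against the antibody group (adjusted p = 1.58e-10, adjusted p = 0.0351 with an estimated correlation), with 7 of 9 higher. Scaled on endothelial markers these medians were -2.84 and 1.63. Against controls the inhibitor group's median was 0.37 (adjusted p = 0.459), and -1.16 scaled, with 5 of 9 lower and 0 higher. Fibroblast markers did the reverse, with medians of 1.12 (adjusted p = 2e-05, adjusted p = 0.0892 with an estimated correlation), -2.55 (3.43e-12, adjusted p = 0.0351 with an estimated correlation) and -1.24 (0.0203, adjusted p = 0.292 with an estimated correlation) in the same order, the last call lost without genes shared with other pathway lists (0.488). Scaled, these medians were 0.73, -3.77 and -2.81.

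Interferon response genes were higher with the inhibitor than in controls, 15 of 23 with a median of 1.37 (-0.22 scaled on endothelial markers, adjusted p = 5.24e-07, adjusted p = 0.273 with an estimated correlation), among them Isg15 by 2.08 ± 0.33. Against the antibody group their median was 0.95 (-0.19 scaled, adjusted p = 4.43e-05, adjusted p = 0.436 with an estimated correlation), with Gbp2, an interferon-induced GTPase, up by 1.62. Without control 3 or inhibitor 2 the count of 15 was 9. Retinal ganglion cell markers were lower with the inhibitor than with the antibodies alone (median -1.01, or -2.26 scaled, adjusted p = 1.99e-04, adjusted p = 0.0642 with an estimated correlation), among them Nefl, which fell by 2.08 on the log2 scale. Microglia and macrophage markers were lower than in controls in both treated groups, with medians of -0.94 (adjusted p = 5.9e-05, adjusted p = 0.324 with an estimated correlation) and -1.58 (8.23e-05, adjusted p = 0.312 with an estimated correlation), and 4 of 18 fell in the antibody group and 12 in the inhibitor group, or 6 without inhibitor 1. Scaled, the medians were -1.13 and -3.14, and with the rod marker share as a covariate both list tests pointed up (0.038 and 0.0198). The antibody libraries differed among themselves. The mean log2 CPM of these markers was 2.55 in antibody 3, near the lowest control (2.61, control 2), against 1.1 in antibody 1 and 1.2 in antibody 2.

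The other lists that passed their test were these, each with its median and then its median scaled on endothelial markers. For the antibodies against controls they were the VEGF and angiopoietin genes (0.31 and -0.12, adjusted p = 0.00271), flow-responsive genes (0.52 and 0.12, 1.6e-04), glycolysis and hypoxia genes (0.23 and -0.16, 0.0017), mitochondrially encoded genes (-0.43 and -0.87, 0.00278), cone markers (-0.98 and -1.28, 1.32e-10) and bipolar cell markers (-0.87 and -1.11, 4.53e-08). With an estimated correlation their adjusted p were 0.324, 0.467, 0.399, 0.508, 0.15 and 0.188, and the mitochondrial list lost its call without antibody 3 (0.076, median -0.24) and the VEGF and angiopoietin list without genes shared with other pathway lists (0.104). With the mural marker share as a covariate the flow list's test pointed down (0.0484). For the inhibitor against the antibodies they were ribosomal protein genes (-0.20 and -1.38, 6.16e-04), bipolar (0.33 and -0.90, 0.0329), amacrine and horizontal (-0.50 and -1.71, 0.0266) and astrocyte markers (-0.50 and -1.71, 0.0133), with adjusted p of 0.729, 0.677, 0.371 and 0.332 with an estimated correlation. The ribosomal list lost its call without antibody 1 (0.212), the bipolar list without antibody 1 (0.124), antibody 2 (0.143, median 0.21) or inhibitor 3 (0.0719), and the amacrine list without antibody 3 (0.0728). The bipolar median was 0.50 without antibody 3.

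For the inhibitor group against controls the endothelial activation genes (0.89 and -0.70, adjusted p = 1.56e-07), immediate early genes (0.43 and -1.15, 4.85e-04), mesenchymal genes (0.54 and -1.07, 0.00629), ribosomal protein genes (0.33 and -1.24, 2.18e-08), VEGF and angiopoietin genes (0.40 and -1.18, 1.83e-04), glycolysis genes (0.26 and -1.33, 0.00106), receptor pathway genes (0.36 and -1.19, 0.0254), histones (0.61 and -0.95, 0.0419) and platelet markers (2.02 and 0.52, 0.00577) passed upward. With an estimated correlation their adjusted p were 0.0782, 0.312, 0.406, 0.469, 0.243, 0.312, 0.292, 0.212 and 0.312. Cone (-1.15 and -2.75, 2.12e-06), bipolar (-0.58 and -2.16, 0.0044), amacrine (-0.83 and -2.42, 0.00233), ganglion cell (-1.11 and -2.70, 9.86e-04) and Muller glia markers (-0.36 and -1.98, 0.0139) passed downward, with adjusted p of 0.283, 0.406, 0.212, 0.092 and 0.292 with an estimated correlation. With the rod marker share as a covariate the bipolar test pointed up (0.00225), and with endothelial scaling the ribosomal test pointed down (0.0187). The histone list lost its call without control 2 (0.0534), antibody 3 (0.0846) or inhibitor 3 (0.0705). Without genes shared with other pathway lists the VEGF and angiopoietin (0.183) and receptor pathway lists (0.365) lost theirs. The p53 target, cholesterol, lens, erythrocyte, lymphatic, T, B and NK cell and neutrophil lists passed in none of the 3 comparisons (adjusted p 0.0547 to 0.982, camera). The lymphatic list did pass for the inhibitor against the antibodies without antibody 1 (0.024), antibody 2 (0.0217), antibody 3 (0.0493) or inhibitor 2 (0.03), and with Y-linked expression as a covariate (0.0328).

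Gt(ROSA)26Sor, the transcript of the locus used for many transgenes, fell by 2.02 ± 0.14 with the antibodies and rose by 1.97 ± 0.14 with the inhibitor added. Pde6h fell by 4.20 and rose by 3.00, a return in part only. All 10 cone markers, Pde6h among them, lay below controls in the inhibitor group (log2 fold changes -2.05 to -0.36). An allele or segment that differs between pools of pups might give this: of 473 genes that changed in the antibody group alone and have a position, 3 lay within 10 Mb of the locus, Camk1 (0.56), Il17rc (1.30) and Efcab12 (-1.14), chosen after their values were seen, and random sets gave a median of 4 and a central range of 1 to 8. The 3 lie inside that range, so that no crowding was seen among these genes within 10 Mb. Only genes within 0.5 of controls on the log2 scale in the inhibitor group entered the set, and Gt(ROSA)26Sor itself was left out. Pde6h was not among the 3, and lowered genes farther along the chromosome were not counted. A segment need not change many genes within 10 Mb, and an allele of the locus alone changes no neighbour, so that the test decides neither. Fewer cone cells in the antibody group cannot alone account for Pde6h, whose change with the inhibitor exceeded the highest of the 9 other cone markers by 2.9. A part of its fall with the antibodies may still go with these markers, which ran from -2.15 to 0.44 there. No biological explanation was tested.

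SMAD1/5 targets were higher with antibodies against the ligands of that pathway. A larger share of endothelial RNA might contribute: after scaling on endothelial markers 1 target was called higher instead of 14, though the target Eng is itself among these markers. The median went from 1.15 to 0.74 as that of all genes went from -0.02 to -0.40, and the median SE from 0.23 to 0.31, so that a shift of all genes and wider errors take the calls away and the test does not decide it. More mural RNA might contribute as well: with mural markers below controls in the inhibitor group, 9 targets were higher and 3 lower, which met the bound set against it. Endothelial markers were higher by 1.52 there, however, which can offset a mural part, so that neither explanation is settled. A response of the pathway itself to the antibodies stays open and untested.

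G2/M genes were as high with the CDK4/6 inhibitor as without it (median -0.03). A larger share of endothelial RNA in the inhibitor libraries could hide a fall: after scaling on endothelial markers 57 of the 58 genes were called lower, but the median of all genes moved by -1.22 and that of the G2/M genes to -1.21, so that the scaling itself fixes the outcome. Less mural RNA in the inhibitor libraries would lower the median of genes that mural cells express. The value of -0.03 lies within the bound set against it, but that bound was written after the same median was seen. Meeting it restates the pattern and cannot decide the question, and endothelial markers higher by 1.11 can offset such a fall. Both stay open, as does a lack of arrest at the day sampled, which was not tested.

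The 6 libraries of each comparison can be split 10 ways, too few for a share under 0.05. The real split called 4177, 2543 and 5562 genes and the highest of the others 0 in each comparison (edgeR), so that 1 of the 10 splits reached the real count.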
